A study of Mus musculus with 6 samples.

How the data were processed

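Gene expression was measured in bone marrow macrophages of wild-type (WT) and knockin (KI) mice after 24 hours with M-CSF at 44 ng/ml and RANKL at 100 ng/ml, with 3 arrays for each genotype. M-CSF keeps macrophage precursors alive and dividing, and RANKL is the cytokine that turns them into osteoclasts, the cells that resorb bone. Biotin-labelled RNA made from the 3' end of the transcripts was hybridised to Affymetrix mouse expression arrays, per the labels' protocols. The deposited table holds 1 intensity for each probe set and array on a linear scale. Per the submitters' processing notes, Affymetrix Expression Console made these values; its version, the summarisation algorithm and the normalization are not given in the sources used here. The scale was read from the values: the median intensity lay between 83.0 and 84.8 on the 6 arrays, and the other quantiles were close, so that the deposited intensities were taken as already normalized between arrays. The number of arrays limits the precision of every value.

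The table had 45101 probe sets, of which 64 control probe sets were left out of the tests. Of the other 45037, the platform annotation paired 34945 with 1 gene symbol and 932 with several, and 9160 had no gene named here. No gene was named from a probe set with several. Of the single-gene probe sets, 34741 matched a reference gene table (assembly GRCm38.p6) by gene identifier, which was used for names and for which genes neighbour each other. Intensities were floored at 16 and log2 transformed, and 5.46% of the deposited values lay below that floor. Probe sets were tested when their mean log2 over the 6 arrays lay above the median of all non-control probe sets, which left 22518.

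The KI and WT arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05; a second criterion also asked for a 2-fold difference. All fold changes are KI against WT. For gene lists, each of 18193 genes was represented by its probe set with the highest mean, without the filter. In the alternative fits that probe set was chosen again from the arrays and probe sets kept, so it can differ between fits. Each of 24 lists was described by the members past the threshold over all genes, by the count adjusted over the list alone, and by limma's camera test with a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and limma's fry were alternatives. The largest changes are given from the fit of probe sets, and members of lists from the fit of genes, so that the values of 1 gene can differ between them, by probe set or by adjusted p. Single values were compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 arrays is 0.1.

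The 24 gene lists, the tests of the report and the naming rule were chosen before the data were examined. The rule took Tnfrsf11a, the 12 largest rises and the 12 largest falls among single-gene probe sets past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, and a fixed set of osteoclast genes; Y-linked and marker genes it took that did not pass are given as counts. Of the genes the rule always names, 1 had no probe set paired with it alone in the annotation used here. The lists were osteoclast effectors, osteoclast fusion, osteoclast transcription factors, repressors of osteoclastogenesis, RANK and co-receptor signalling, NF-kB target genes, interferon-stimulated genes, macrophage identity, antigen presentation and dendritic cells, cell cycle, oxidative phosphorylation, V-ATPase subunits, lysosomal hydrolases, glycolysis and hypoxia, cholesterol synthesis, unfolded protein and integrated stress response, matrix and adhesion, sex-linked genes, and markers of neutrophils and myeloid progenitors, mast cells and basophils, B cells, T and NK cells, erythroid cells and megakaryocytes, and stromal cells and osteoblasts.

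The same steps were tested on simulated arrays drawn from the measured means and within-group SDs, over 22518 probe sets. Of 67 probe sets changed by 0.5 on the log2 scale, 32.8% were recovered; of 67 changed by 1, 70.1%; and of 66 changed by 2, 89.4%, with 5 calls among unchanged probe sets. These simulated arrays held independent noise, so they do not carry any deviation shared by many genes of an array. Among simulated lists, the shifted list was called and 0 of 23 unshifted lists were.

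Alternatives were quantile normalization, a common median, no filter, a filter to the top 30% of probe sets, log2 of the intensity plus 32, other variance priors, array weights, the replicate number as a block, the number in the sample descriptions as a covariate, the 3 arrays with consecutive such numbers alone, leaving out each array, 1 mean per gene, and leaving out probe sets that can match several transcripts. The estimation of the array weights stopped before convergence, so every count and p-value given with array weights is less certain. The 3 arrays with consecutive numbers were WT 1, WT 2 and KI 1. That fit holds 1 KI array, so its p-values are not given. Its count of probe sets past the threshold is listed only with the other processing settings and does not measure stability. A scaling to the hybridisation spike-ins, a scaling to the older probe sets for the same spike-ins and a fit without WT 1 and KI 1 were added after seeing the data. The labels do not say whether the replicates were separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.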

Results

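The series set bone marrow macrophages of knockin mice against those of wild-type mice, both on a C57BL/6 background per the labels, after 24 hours of M-CSF and RANKL. Its title names the IVVY motif of RANK, a stretch of the cytoplasmic part of the RANKL receptor, and the comparison asks which genes depend on that motif early in osteoclast formation. The labels do not describe the altered residues. There were 3 WT and 3 KI arrays, and the median intensity of an array ranged from 83.0 to 84.8.

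KI arrays lay apart from WT arrays along the first principal component, which held 82.2% of the variance of the tested probe sets. Within the groups, WT 1 and KI 1 lay farthest out, with scores of -66.5 and 54.0. WT 2 and WT 3 scored -30.1 and -29.4, and KI 2 and KI 3 scored 32.1 and 39.9. The closest arrays were WT 2 and WT 3 (Pearson r = 0.997 across probe sets), and no pair was identical.

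**Figure D1:**
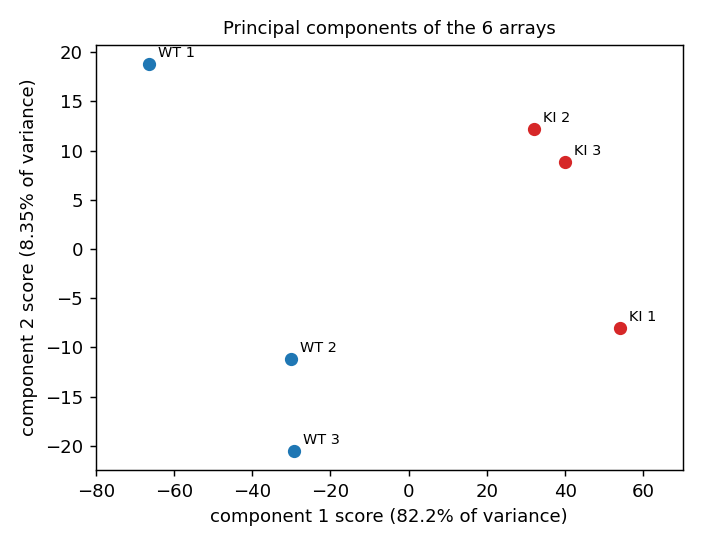
Scores of the 6 arrays on the first principal component (x axis, 82.2% of variance) and the second (y axis, 8.35%), in arbitrary units, 1 point per array, blue for WT and red for KI. The 3 WT arrays score between -66.5 and -29.4 on the first component and the 3 KI arrays between 32.1 and 54.0.

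Tnfrsf11a, which encodes RANK, gave opposite estimates from its 2 probe sets. The probe set brighter in WT had a mean intensity of 484 ± 77.2 (SD, n = 3) in KI and 1056 ± 82.6 (SD, n = 3) in WT. It fell by 1.13 on the log2 scale (SE 0.13, adjusted p = 0.0015 by limma). The other probe set had a mean intensity of 961 ± 119 (SD, n = 3) in KI and 847 ± 258 (SD, n = 3) in WT, a log2 difference of 0.22 (SE 0.22, adjusted p = 0.45 by limma). Without WT 1, that difference was 0.45 and passed the threshold (adjusted p = 0.040), and without WT 2 it was 0.03 (adjusted p = 0.92). It turned to -0.31 (adjusted p = 0.32) under a scaling to spike-in probe sets described below as older spike-in scaling. The parts of the transcript that these probe sets cover were not analysed here, so neither value checks the labels of the samples.

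With each gene taken by its probe set with the smallest p, Slco2b1, Slc40a1 and Ednrb had the largest rises in KI cells, and Spint2, Slc6a12 and Akap6 the largest falls. Slco2b1, an organic anion transporter, rose by 4.28 on the log2 scale, a 19.5-fold change (SE 0.39, adjusted p = 0.00070), on 1 of its 3 probe sets. Another of them also rose, the last did not pass, and with 1 mean per gene the rise was 1.83. Slc40a1, the cellular iron exporter ferroportin, rose by 3.07 (SE 0.42, adjusted p = 0.0024), and Cd163, the haemoglobin-haptoglobin scavenger receptor, by 2.62 (SE 0.20, adjusted p = 0.00048). The other large rises on the log2 scale were those of the endothelin receptor Ednrb (3.05), Fcrls (2.86), Gpr34 (2.50), Ctla2b (2.49), the growth factor Igf1 (2.48), the fatty acid scavenger receptor Cd36 (2.47), Cbr2 (2.46), Cnrip1 (2.44) and Samd4 (2.43). Spint2, a membrane inhibitor of serine proteases, had the largest fall, with a log2 change of -3.93 (SE 0.16, adjusted p = 0.00020). Traf1, an adaptor of the tumour necrosis factor receptor family, fell by 2.95 (SE 0.08, adjusted p = 6.1e-05), and Mmp9, a matrix metalloproteinase abundant in osteoclasts, fell by 2.89 (SE 0.13, adjusted p = 0.00020). The remaining large falls were those of the betaine transporter Slc6a12 (-3.45), Akap6 (-3.32), Gstt1 (-3.28), the myo-inositol transporter Slc5a3 (-3.03), the serotonin transporter Slc6a4 (-2.98), Celsr1 (-2.87), Adig (-2.85), the transcription factor Bhlhe40 (-2.83) and 1700012B09Rik (-2.73). Of the probe sets of Akap6 1 of 2 fell, and of those of Samd4 3 of 4 rose. The fit of genes, which takes the brightest probe set, used another probe set for some of these genes, with 1.17 for Slco2b1, 2.91 for Slc40a1, 2.31 for Igf1, 2.26 for Cd36, 2.74 for Cnrip1, -2.62 for Spint2, -3.18 for Traf1 and -2.33 for Slc5a3. Without WT 1 and KI 1 the rise of Ednrb was 2.02 and that of Gpr34 1.44.

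Across the genome, 10101 of 22518 tested probe sets (44.9%) differed between KI and WT, 4345 higher and 5756 lower in KI. Of these, 1836 differed at least 2-fold, 944 higher and 892 lower. The groups did not overlap for 60.9% of tested probe sets, where chance gives 10% on average over the splits of the arrays. Where probe sets move together, 1 split can reach a far higher share by chance, so the 10% does not measure that. The median absolute log2 change of the probe sets called was 0.57. After scaling to the hybridisation spike-ins, a setting chosen after seeing the data, 2546 were higher and 9011 lower (601 and 1540 at least 2-fold), and the median of all tested probe sets moved from -0.04 to -0.25. With the older probe sets for the same spike-ins (older spike-in scaling, also chosen after seeing the data), 728 were higher and 10586 lower (300 and 3793 at least 2-fold), and the median moved to -0.57. Directions below are those of the deposited values. Without WT 1 and KI 1, 1122 probe sets differed at least 2-fold, and with the number in the sample descriptions as a covariate 6481 passed the threshold. A fit to the 3 arrays with consecutive numbers (WT 1, WT 2 and KI 1) holds 1 KI array, so its count is not compared here. The call for Gpr34 ended without KI 1 (adjusted p = 0.063), without KI 3 (adjusted p = 0.053), with the covariate (adjusted p = 0.068) and without the filter (adjusted p = 0.073).

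Of 22 osteoclast effector genes measured, 9 fell in KI cells, 3 rose and 10 did not pass the test; adjusted over the list alone, 9 fell and 4 rose. Spike-in scaling gave 11 lower and 1 higher, and older spike-in scaling 14 and 0. Acp5, the tartrate-resistant acid phosphatase used to stain osteoclasts, fell by 0.92 on the log2 scale (SE 0.05, adjusted p = 0.0010), and Ctsk, the protease cathepsin K that digests bone collagen, fell by 0.70 (SE 0.11, adjusted p = 0.0092). Src, a kinase required for the resorbing surface, fell by 1.77 (SE 0.09), and Mmp14 fell by 1.15 (SE 0.07). The list was lower than other genes (camera adjusted p = 0.030; adjusted p = 0.41 with an estimated correlation). Calcr, the calcitonin receptor, lay near the floor in both groups (log2 difference 0.23, adjusted p = 0.081; 0.047 with the covariate; -0.30 under older spike-in scaling). The integrin gene Itgb3 differed by 0.00 (SE 0.22), and by -0.53 (adjusted p = 0.069) under that scaling.

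Of 20 transcription factor genes of osteoclast formation measured, 9 fell, 3 rose and 8 did not pass (12 and 3 adjusted over the list alone). Nfatc1, the master regulator of the lineage, fell by 1.00 (SE 0.09, adjusted p = 0.0028), and Fos, which acts upstream of it, fell by 1.08 (SE 0.10, adjusted p = 0.0029). Another Nfatc1 probe set, with a mean log2 of 11.06, differed by -0.21 (adjusted p = 0.23 by limma over all probe sets). The remaining probe sets of Nfatc1 differed by -1.05 to -1.24. Prdm1, a repressor of anti-osteoclastogenic genes, fell by 1.55 (SE 0.07), Jdp2 by 1.24 (SE 0.06), Fosl2 by 1.28 (SE 0.07) and Ppargc1b, a coactivator of mitochondrial genes, by 1.35 (SE 0.08). The list was lower than other genes (camera adjusted p = 0.011; adjusted p = 0.41 with an estimated correlation). The camera calls of both lists ended without WT 1 (adjusted p = 0.084 for effectors and 0.055 for transcription factors), and that of the effectors also without KI 2 (adjusted p = 0.059). Spike-in scaling ended both as well (adjusted p = 0.078 and 0.081), and the covariate that of the effectors (adjusted p = 0.10). Both also ended without WT 1 and KI 1 (0.056 each). Over the alternatives with the preset correlation the adjusted p ranged from 0.00019 to 0.10 for effectors and from 0.00050 to 0.081 for transcription factors. Of the transcription factors 1 rose without KI 1, without KI 3, with the covariate or under older spike-in scaling, and 5 with array weights; 12 fell under either spike-in scaling.

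**Figure D2:**
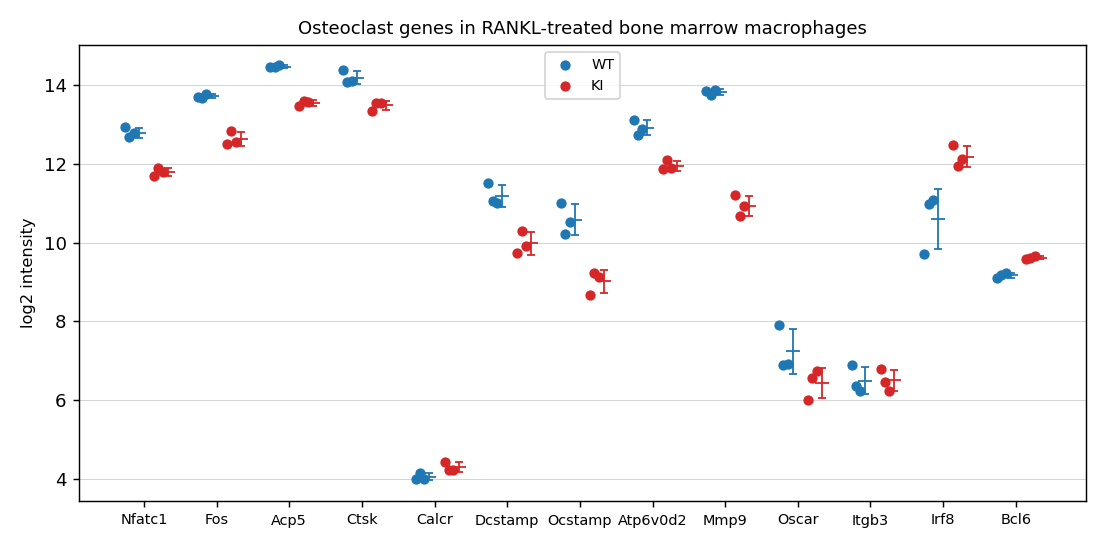
Log2 intensity (y axis) of 13 genes named in advance (x axis) on each of the 3 WT arrays (blue points) and 3 KI arrays (red points), with the mean and SD of each group beside the points. Every KI value lies below every WT value for Nfatc1, Fos, Acp5, Ctsk, Dcstamp, Ocstamp, Atp6v0d2, Mmp9 and Oscar, whose difference did not pass the test, and above it for Calcr (also not past the test), Irf8 and Bcl6, all as deposited; under older spike-in scaling the differences turn to -0.30 for Calcr and -0.077 for Bcl6.

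Fusion genes split between directions. Dcstamp and Ocstamp, membrane proteins required for cell-cell fusion, fell by 1.21 (SE 0.20, adjusted p = 0.012) and 1.57 (SE 0.24, adjusted p = 0.0098), as did Sbno2 by 0.84 (SE 0.10). The tetraspanin Cd81 rose by 1.04 (SE 0.11) and Ebi3 by 1.64 (SE 0.23). Of 12 fusion genes measured, 4 fell, 3 rose and 5 did not pass, with 4 and 3 adjusted over the list alone (camera adjusted p = 0.76). The call for Dcstamp ended without KI 3 (adjusted p = 0.053), where 2 fusion genes fell. With the covariate the calls for Dcstamp (0.057) and Ebi3 (0.052) ended, with 1 fusion gene higher, and under older spike-in scaling that for Cd81 (0.51, adjusted p = 0.082). Of 17 V-ATPase subunits, parts of the proton pump, 4 fell and 3 rose, or 5 and 3 adjusted over the list alone, but 8 fell and 1 rose under spike-in scaling and 9 fell and 1 rose under older spike-in scaling (as deposited, camera adjusted p = 0.48), with a median of -0.06 and a mean of 0.00 that differed in sign. Atp6v0d2, the osteoclast-enriched subunit, fell by 0.97 (SE 0.12, adjusted p = 0.0056), and Atp6v0a1 rose by 1.56 (SE 0.20, adjusted p = 0.0063). Atp6v0d1 (0.41) and Atp6v1d (-0.23) passed with all 6 arrays but neither passed without KI 1 (adjusted p = 0.061 and 0.082) or KI 3 (0.071 and 0.068), nor Atp6v1d without WT 2 (0.069), WT 3 (0.065) or KI 2 (0.065). Of V-ATPase subunits, 1 rose without KI 1 or KI 3, and 1 to 2 fell when any of WT 1, WT 2, WT 3, KI 1, KI 2 or KI 3 was left out. With array weights 7 fell, and 2 with quantile normalization, where Atp6v1d did not pass (0.053), nor did it without WT 1 and KI 1 (0.051), where 2 fell, as without probe sets that can match several transcripts. Atp6v0a1 rose by 0.75 with 1 mean per gene. The covariate ended the calls for Atp6v0a1 (0.053), Atp6v0d1 (0.099) and Atp6v1d (0.12), with 0 subunits higher and 1 lower, and under older spike-in scaling Atp6v0d1 turned to -0.12.

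Repressors of osteoclast formation included genes that rose in KI cells. Irf8, a transcription factor that holds NFATc1 in check, rose by 1.58 (SE 0.40, adjusted p = 0.037), Bcl6 by 0.45 (SE 0.06, adjusted p = 0.0063) and Rbpj, the Notch effector, by 0.78 (SE 0.06, adjusted p = 0.0022). Tnfaip3, a deubiquitinase induced by NF-kB, fell by 1.33 (SE 0.06, adjusted p = 0.0010). Of 18 genes measured, 5 rose, 2 fell and 11 did not pass (6 and 2 adjusted over the list alone; camera adjusted p = 0.15). That balance turned to 3 higher and 4 lower under spike-in scaling and 3 and 5 under older spike-in scaling, while 10 rose with array weights and 8 with log2 of the intensity plus 32 or without WT 1 and KI 1. The call for Irf8 ended without WT 2 (adjusted p = 0.061), KI 1 (0.11), KI 2 (0.077) or KI 3 (0.10), and spike-in scaling ended that for Bcl6 (adjusted p = 0.082). Under older spike-in scaling Bcl6 turned to -0.077, and the call for Rbpj ended (0.25, adjusted p = 0.39). The covariate ended the calls for Irf8 (0.13), Bcl6 (0.055) and Cyld (0.10), with 1 gene higher and 1 lower. Cyld fell by 0.31 (SE 0.06, adjusted p = 0.015), a call that ended without KI 2 (0.053) or KI 3 (0.067) and with 1 mean per gene (-0.10, adjusted p = 0.32), where 1 gene fell. Irf8 rose by 0.99 without WT 1 and KI 1. The list passed with array weights (camera adjusted p = 0.048), without WT 1 and KI 1 (0.017), under spike-in scaling (0.0037) and under older spike-in scaling (0.0010). In each pass it was higher than other genes, although its median turned from 0.43 to -0.097 under older spike-in scaling. Of its genes 2 rose without WT 2 or KI 3 and 3 without KI 1, and 1 fell without KI 2 or KI 3.

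Genes of RANK signalling and NF-kB targets changed in both directions. In the fit of genes, by another probe set than above, Traf1 fell by 3.18 (SE 0.08), and Traf2, another adaptor of this receptor family, fell by 1.20 (SE 0.09, adjusted p = 0.0020). The co-receptor Trem2 rose by 1.60 (SE 0.17, adjusted p = 0.0044) and the kinase Tec by 0.85 (SE 0.06, adjusted p = 0.0018), and the co-receptor Oscar had a log2 difference of -0.81 (SE 0.34, adjusted p = 0.14; 0.037 under spike-in scaling). The rise of Trem2 rested on a probe set that can match several transcripts, and with such probe sets left out the gene differed by 0.09 (adjusted p = 0.60), and by 0.84 with 1 mean per gene. Under older spike-in scaling Oscar passed (-1.34), and the call for Tec ended (0.32, adjusted p = 0.27), with 1 signalling gene higher and 8 lower. Of 28 signalling genes, 10 rose, 4 fell and 14 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 0.25). Without WT 2, KI 1 or KI 2, 5 signalling genes rose, and 4 without KI 3, under spike-in scaling 6 rose and 7 fell, and with the covariate 2 rose. Among 32 NF-kB target genes, 9 rose and 10 fell, or 9 and 11 adjusted over the list alone (camera adjusted p = 0.76), with 14 higher with array weights and 4 higher and 6 lower with the covariate. Nfkb2, the precursor of the non-canonical NF-kB subunit, fell by 1.47 (SE 0.09, adjusted p = 0.0012) and Birc2 by 1.53 (SE 0.09, adjusted p = 0.0012), while the chemokine Ccl4 rose by 1.59 (SE 0.08, adjusted p = 0.0010). Of 32 interferon-stimulated genes 3 rose and 3 fell, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.17). Oasl1 fell by 0.69 (SE 0.06) and Cxcl9 by 1.10 (SE 0.15), or 0.56 with 1 mean per gene. Rsad2 (0.52) and Mx2 (0.40) passed with all 6 arrays, but not without WT 2 (adjusted p = 0.057 and 0.084), KI 1 (0.075 and 0.095) or KI 3 (0.084 and 0.11), nor Mx2 without WT 1 (0.066), and neither without WT 1 and KI 1 (0.072 and 0.13). With the covariate the calls for Cxcl9 (0.057), Rsad2 (0.10) and Mx2 (0.13) ended, and under older spike-in scaling Rsad2 turned to -0.0073 and Mx2 to -0.13. Without WT 2, KI 1 or KI 3, 0 interferon-stimulated genes rose, and with the covariate 0 rose and 1 fell. Without WT 1, 6 interferon-stimulated genes rose, as did 7 with the common median, log2 of the intensity plus 32 or robust eBayes and 14 with array weights, where 6 fell. Under spike-in scaling 5 rose and 7 fell. The list passed as higher than other genes without WT 3 (camera adjusted p = 0.041) and under spike-in scaling (0.035), although spike-in scaling turned its median from 0.17 to -0.03. Under older spike-in scaling the median was -0.36, and 0 of its genes rose and 9 fell.

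Macrophage genes were higher in KI cells. Tlr2, a receptor for bacterial lipoproteins, rose by 1.60 (SE 0.08, adjusted p = 0.0010), Cd36 by 2.26 (SE 0.14, adjusted p = 0.0012), Vsig4, a complement receptor, by 1.84 (SE 0.15, adjusted p = 0.0023) and the lectin Clec4d by 1.07 (SE 0.08, adjusted p = 0.0021). Of 34 macrophage identity genes, 24 rose, 0 fell and 10 did not pass, with 30 higher adjusted over the list alone. With the covariate 7 rose, and 5 with the replicate number as a block. Under older spike-in scaling 17 rose and 1 fell, with a median of 0.54. The median log2 change was 1.07 (camera adjusted p = 2.8e-11; adjusted p = 0.41 with an estimated correlation). The mean of the list on WT 1 was -0.97 on the centred log2 scale, against -0.35 on WT 2 and -0.31 on WT 3, and 0.61, 0.50 and 0.53 on the KI arrays. Lysosomal hydrolases and membrane proteins rose too, 21 of 26 with 0 falls, or 24 adjusted over the list alone. Their median was 0.46, which turned to -0.074 under older spike-in scaling, where 2 rose and 1 fell, against 12 and 1 under spike-in scaling (camera adjusted p = 1.5e-08 as deposited; adjusted p = 0.41 with an estimated correlation). The proteases Ctsc and Ctsl rose by 0.69 (SE 0.09) and 0.45 (SE 0.07), and Npc1, which exports cholesterol from lysosomes, by 0.45 (SE 0.07). Counts of macrophage genes that rose were 14 without WT 2 and 8 without KI 1, KI 2 or KI 3, and those of lysosomal genes 12 without WT 2, 7 without KI 1, 9 without KI 2 and 3 without KI 3, with fewer arrays in each fit. With the covariate or with the block 1 lysosomal gene rose, and 1 fell with array weights or without WT 1 and KI 1. Gusb rose by 0.29 (SE 0.05, adjusted p = 0.012), which ended without KI 3 (0.057), under spike-in scaling (0.49) and with 1 mean per gene (0.13, adjusted p = 0.21). Ctsc rose by 1.08 with 1 mean per gene, and Ctsl by 0.79 without probe sets that can match several transcripts. Under spike-in scaling Ctsl and Npc1 kept a positive difference of 0.25 each without passing the threshold (adjusted p = 0.095 and 0.088). Under older spike-in scaling Ctsl (-0.075), Npc1 (-0.078) and Gusb (-0.24) turned negative, and the calls for Clec4d (0.54, adjusted p = 0.054) and Ctsc (0.16, adjusted p = 0.54) ended. The covariate ended those for Ctsc (0.051), Ctsl (0.062) and Gusb (0.067).

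No gene of the cell cycle, oxidative phosphorylation and glycolysis and hypoxia lists rose in KI cells. Cdc6, which licenses replication origins, fell by 1.42 (SE 0.23, adjusted p = 0.011), and 14 of 42 cell cycle genes fell, 0 rose and 28 did not pass, with 18 lower adjusted over the list alone, 5 with the covariate, 27 with array weights, 30 under spike-in scaling and 42 under older spike-in scaling. The list median was -0.73 (camera adjusted p = 3.9e-07; adjusted p = 0.64 with an estimated correlation and 0.12 with fry), and the list mean ranged from -0.86 on KI 1 to -0.02 on KI 2 and from 0.22 on WT 3 to 0.69 on WT 1. Rrm2 (-1.58), Ccne2 (-1.69) and Mcm7 (-0.99) fell with all 6 arrays in the fit, but not without WT 1 (adjusted p = 0.055, 0.062 and 0.063), WT 2 (0.059, 0.051 and 0.061) or KI 3 (0.065, 0.083 and 0.076). Ccne2 and Mcm7 did not pass without WT 3 (0.062 and 0.056), nor Ccne2 without KI 1 (0.056). The covariate ended the calls for Cdc6 (0.063) and Ccne2 (0.057), and that for Ccne2 ended without WT 1 and KI 1 (0.071). With the replicate number as a block 0 cell cycle genes fell. The count of cell cycle genes that fell was 2 without WT 1, 1 without WT 2 or KI 3, 3 without WT 3 and 6 without KI 1, where the median was -0.47. Of 41 oxidative phosphorylation genes, 31 fell, 0 rose and 10 did not pass, with 35 lower adjusted over the list alone, 40 lower under either spike-in scaling and a median of -0.29 (camera adjusted p = 1.7e-12; adjusted p = 0.41 with an estimated correlation). Cyc1, the cytochrome c1 of complex III, fell by 0.88 (SE 0.07, adjusted p = 0.0023), and Idh3a, a subunit of a citric acid cycle dehydrogenase, by 1.40 (SE 0.15, adjusted p = 0.0044). Sdhd and Uqcrc1, of complexes II and III, fell by 0.41 and 0.38. Of the list, 19 genes fell without KI 3 or with the covariate, and 0 with the replicate number as a block. Glycolysis and hypoxia genes fell in 15 of 23 cases and rose in 0, with 17 lower adjusted over the list alone or under spike-in scaling, 19 under older spike-in scaling and a median of -0.74 (camera adjusted p = 3.5e-05; adjusted p = 0.41 with an estimated correlation). Tpi1 and Ldha, enzymes of glycolysis and lactate formation, fell by 0.84 (SE 0.09) and 0.75 (SE 0.10), and Pgk1 by 0.52. Adm fell by 1.01 (adjusted p = 0.0062), with values of -1.66 without KI 2 and -1.67 without KI 3 (adjusted p = 0.051), and -1.78 without probe sets that can match several transcripts. The brightest probe set was chosen again in each of these fits. These values therefore reflect a change of probe set and do not show an effect of the array left out. The count of glycolysis and hypoxia genes that fell was 9 without WT 3, 6 without KI 3, 8 with the covariate and 4 with the block.

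Cholesterol synthesis genes rose in 5 of 20 cases and fell in 0, also adjusted over the list alone, with a median of 0.46, which turned to -0.074 under older spike-in scaling, where 0 rose and 1 fell, against 2 and 0 under spike-in scaling (camera adjusted p = 0.00055 as deposited; adjusted p = 0.64 with an estimated correlation and 0.22 with fry). Tm7sf2, a sterol reductase, rose by 0.84 (SE 0.12, adjusted p = 0.0082). The list mean on KI 1 (-0.12) lay below that on WT 1 (0.04), and the camera call ended with the description number as a covariate (adjusted p = 0.083). The count of genes that rose was 1 without WT 2, WT 3, KI 2 or KI 3 and 9 without KI 1. It was 18 without WT 1 and KI 1, 17 with array weights and 0 with the covariate or with the replicate number as a block. Insig1 (0.80) and Hmgcs1 (0.63) passed with all 6 arrays, but not without WT 2 (adjusted p = 0.060 and 0.094), WT 3 (0.057 and 0.092), KI 2 (0.058 and 0.081) or KI 3 (0.072 and 0.11). The calls for Tm7sf2, Insig1 and Hmgcs1 ended with the covariate (adjusted p = 0.060, 0.11 and 0.17) and under older spike-in scaling (0.30, 0.37 and 0.73), and that for Hmgcs1 with 1 mean per gene (0.054). In the unfolded protein and integrated stress response list 6 of 21 genes fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.19). Chac1 fell by 2.50 (SE 0.46, adjusted p = 0.016), Asns, which makes asparagine, by 2.12 (SE 0.42, adjusted p = 0.019), Trib3 by 1.01 (SE 0.14, adjusted p = 0.0081) and Atf4, the transcription factor that induces them, by 0.82 (SE 0.16, adjusted p = 0.018). The calls for Chac1, Asns and Atf4 ended without KI 3 (adjusted p = 0.052, 0.052 and 0.060), and those for Chac1 and Atf4 without KI 1 (0.053 and 0.059). The covariate ended those for Chac1 (0.065), Trib3 (0.058) and Atf4 (0.072), with 0 genes higher and 1 lower. The list passed, as lower than other genes, with the covariate (camera adjusted p = 0.049) and under older spike-in scaling (0.016). Of the list, 1 gene fell without KI 3, and 0 rose without KI 1, KI 2 or KI 3. With array weights 5 rose, and 4 without WT 1 and KI 1, while 7 fell under spike-in scaling and 11 under older spike-in scaling. In the matrix and adhesion list 5 of 23 genes rose and 2 fell, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.17). Spike-in scaling gave 5 higher and 4 lower and older spike-in scaling 3 and 7, array weights 11 and 4. With 1 mean per gene 3 rose, and without probe sets that can match several transcripts or with the covariate 1 fell. The integrin gene Itgb5 rose by 1.60 (SE 0.14), the actin-severing gene Gsn by 0.50 (SE 0.05) and the kinase gene Ptk2b by 0.78 (SE 0.08; 0.36 with 1 mean per gene, where the call ended, adjusted p = 0.10), and the focal adhesion gene Pxn fell by 0.52 (SE 0.05). The matrix list passed with fry (adjusted p = 0.031), without WT 1 (camera adjusted p = 0.047), with array weights (0.048) and under spike-in scaling (0.0037). It passed under older spike-in scaling as well (0.016). In each of these passes the test direction was upward, although under older spike-in scaling the median turned from 0.31 to -0.22. There Gsn turned to -0.030 and the call for Ptk2b ended (0.25, adjusted p = 0.40).

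**Figure D3:**
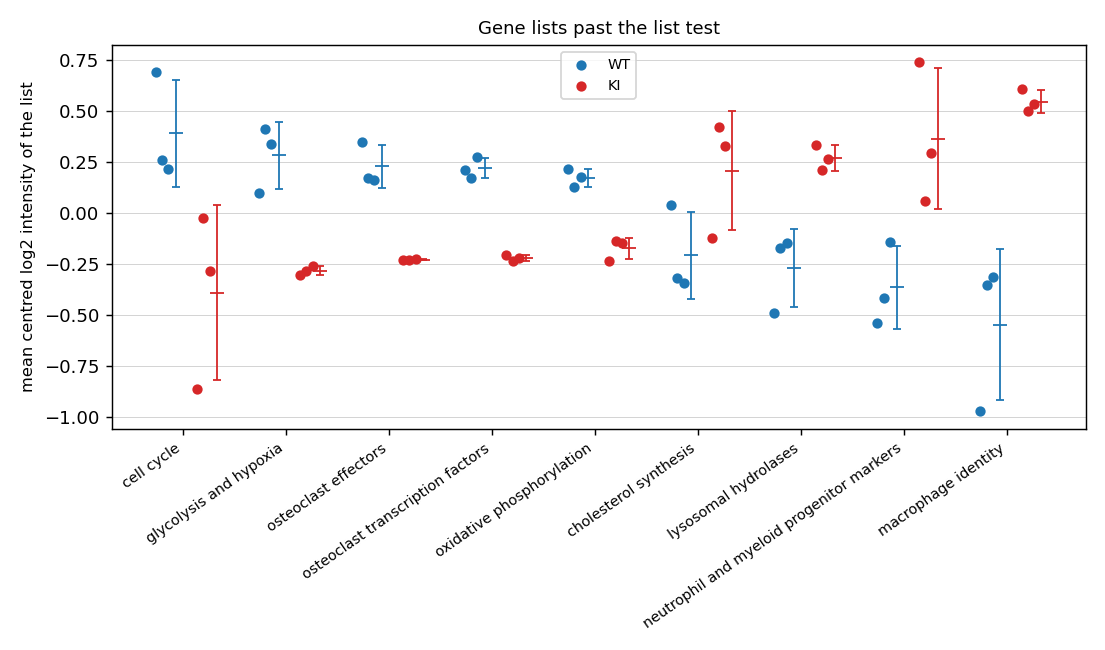
Mean centred log2 intensity (y axis) of the 9 gene lists past the camera threshold with the preset correlation (x axis), on each of the 3 WT arrays (blue points) and 3 KI arrays (red points), with the mean and SD of each group beside the points. As deposited, KI and WT arrays do not overlap except for cholesterol synthesis, where KI 1 (-0.12) lies below WT 1 (0.04); the median differences of cholesterol synthesis and lysosomal hydrolases, positive as deposited, both turn to -0.074 under older spike-in scaling.

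Of 17 neutrophil and myeloid progenitor markers, 2 rose and 15 did not pass, with 11 higher adjusted over the list alone and a median of 0.83 (camera adjusted p = 0.00041; adjusted p = 0.64 with an estimated correlation and 0.079 with fry). Mmp8, a neutrophil collagenase, rose by 1.57 (SE 0.24, adjusted p = 0.0090), and the list mean was highest on KI 1 (0.74) and lowest on WT 1 (-0.54). S100a8 rose by 0.84 (adjusted p = 0.046). That call ended without WT 1 (0.12), WT 2 (0.12), WT 3 (0.080), KI 1 (0.079) or KI 3 (0.13), with the covariate (0.065), without WT 1 and KI 1 (0.13), with eBayes without trend (0.050) and under older spike-in scaling (0.25). The covariate also ended the call for Mmp8 (0.051). Camp (1.00, adjusted p = 0.057) passed without KI 2 (0.031), with the covariate (0.0499), quantile normalization (0.047), the common median (0.032), log2 of the intensity plus 32 (0.029), robust eBayes (0.033) or array weights (0.0052) and under spike-in scaling (0.025). Csf3r (1.98, adjusted p = 0.060) passed without WT 1 (1.31, adjusted p = 0.013) and without WT 1 and KI 1 (1.15, adjusted p = 0.0093). It also passed with the common median (0.035), log2 of the intensity plus 32 (0.024), robust eBayes (0.034) or array weights (1.37, adjusted p = 0.0048), under spike-in scaling (0.016) and under older spike-in scaling (1.45, adjusted p = 3.5e-06). Of these markers 1 rose without WT 2, WT 3, KI 1 or KI 3, with the covariate, with eBayes without trend or without probe sets that can match several transcripts, and 7 without KI 2. Counts of 6 with the common median or robust eBayes, 8 with log2 of the intensity plus 32 or spike-in scaling and 11 with array weights were higher, and older spike-in scaling gave 2 higher and 1 lower. In the antigen presentation and dendritic cell list 5 of 20 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.094). That list passed without WT 3 (camera adjusted p = 0.020), without KI 3 (0.032), with the covariate (0.015), under spike-in scaling (0.0037) and under older spike-in scaling (0.012). In each pass it was higher than other genes. Its median nevertheless turned from 0.04 to -0.16 under spike-in scaling and to -0.49 under older spike-in scaling. Spike-in scaling gave 4 higher and 1 lower, and older spike-in scaling 1 and 4. Cd209a (0.38), Cd1d1 (0.73), Batf3 (1.09) and Kmo (1.31) rose with all 6 arrays in the fit, but each call ended without KI 3 (adjusted p = 0.058, 0.070, 0.050 and 0.080). Further calls ended without WT 2 for Cd209a (0.050), Cd1d1 (0.053) and Kmo (0.061), without KI 1 for Cd1d1 (0.060), Batf3 (0.067) and Kmo (0.052), without KI 2 for Batf3 (0.062), and without WT 1 (0.060) or WT 3 (0.052) for Kmo. The covariate ended all 4 (0.062, 0.093, 0.074 and 0.055), with 0 genes higher, and under older spike-in scaling Cd209a turned to -0.15 and the calls for Cd1d1 (adjusted p = 0.50) and Batf3 (0.066) ended. Without WT 1 and KI 1, where 2 genes rose, those for Cd209a (0.062) and Cd1d1 (0.054) ended, and Batf3 rose by 0.72 with array weights, where 1 gene of the list fell. In this list 3 genes rose without WT 1 or KI 2 and 1 without WT 2, KI 1 or KI 3. Kit fell by 0.50 (SE 0.06) among 11 mast cell and basophil markers, Pf4, a platelet chemokine, rose by 1.72 (SE 0.15) among 12 erythroid and megakaryocyte markers, and Dcn, which encodes the matrix proteoglycan decorin, fell by 1.44 (SE 0.13) among 19 stromal and osteoblast markers, each the 1 call of its list, also adjusted over the list alone. With 1 mean per gene the values were -0.24 for Kit and -0.82 for Dcn. Without KI 3, 2 erythroid and megakaryocyte markers rose. Ighm rose by 1.63 (SE 0.44, adjusted p = 0.045) among 13 B cell markers, of which 0 passed adjusted over the list alone, and its call ended without WT 2 (adjusted p = 0.098), KI 1 (0.13), KI 2 (0.085) or KI 3 (0.11), with the covariate (0.13), without WT 1 and KI 1 (0.056) and with 1 mean per gene (0.31, adjusted p = 0.11), and another of its probe sets differed by 0.05. None of 14 T and NK cell markers and none of 5 sex-linked genes passed in limma, over all genes or adjusted over the list alone. The camera adjusted p of these 6 lists lay at 0.48 or above, but erythroid and megakaryocyte markers passed with fry (adjusted p = 0.037), and for mast cells and basophils the median (0.05) was positive while the mean (-0.03) and the test were negative. Under older spike-in scaling 5 mast cell and basophil markers fell, as did 4 B cell, 5 T and NK cell, 4 erythroid and megakaryocyte and 4 stromal and osteoblast markers and 3 of the 5 sex-linked genes. Of the sex-linked genes 1, Kdm5d, fell without KI 2 (-0.36, adjusted p = 0.043). Spike-in scaling gave 2 mast cell and basophil markers and 1 B cell marker lower, and 1 T and NK cell marker rose without WT 1 and KI 1. With array weights 2 mast cell and basophil markers fell, 2 B cell and 2 erythroid and megakaryocyte markers rose and 1 of each fell, and 1 T and NK cell marker, 1 stromal and osteoblast marker and 1 sex-linked gene rose. Without probe sets that can match several transcripts the call for Ighm ended (adjusted p = 0.73), and Kit was not measured. Y-linked probe sets were at most 27.4 and Xist at least 14300 in intensity on each array.

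RNA quality controls overlapped between the genotypes. The log2 difference between the 3' and 5' control probe sets of Gapdh was -0.10 ± 0.01 in KI and -0.07 ± 0.03 in WT (SD, n = 3 each; two-sided exact permutation p = 0.2), and that of Actb was 0.17 ± 0.01 in both groups (exact permutation p = 0.7). Genes within 20 Mb of Tnfrsf11a were not called more often than others, which bears only on nearby effects of donor-strain sequence around a targeted gene. Of 89 such genes 38 were called (42.7%), against 5194 of 10815 elsewhere (48.0%; odds ratio 0.81, two-sided Fisher's exact test p = 0.34).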

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

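The tests of processing order, of RNA degradation, of the direction in which WT 1 lies and of the spike-in scaling were chosen after the related values were seen, and so was the bound on the odds ratio of the planned test of genes near Tnfrsf11a. The hybridisation spike-ins, bacterial and phage transcripts added to the labelled RNA, were higher in KI by 0.21 on the log2 scale, from 11.23 ± 0.07 in WT to 11.43 ± 0.08 in KI (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). The older probe sets for these transcripts were higher by 0.53, from 10.49 ± 0.31 in WT to 11.02 ± 0.08 in KI (SD, n = 3 each), with every KI array above every WT array. The WT arrays spread widely on these probe sets (10.40, 10.84 and 10.24 on WT 1, WT 2 and WT 3), so the size of this scaling is imprecise. Of the probe sets called higher in KI as deposited, 58.5% (2542 of 4345) were still called higher after scaling to the spike-ins, and 16.3% (707) after scaling to the older probe sets. The controls do not show whether KI arrays received more spike-in or gave less signal from cell RNA, and the 2 kinds of probe set shifted by different amounts, so the size of a common shift, and the between-array normalization as a source of most of the calls higher in KI, stay open.

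The number of differing probe sets underlies all other results. In limma, 10101 probe sets passed in the real split of the 6 arrays and 1836 of them were at least 2-fold apart. The highest count in the other splits was 0, and they held 57 to 430 at an unadjusted p under 0.05. As many passed in 1 of 10 splits, the real one, and 10 splits are too few for a share under 0.05. Each other split mixed the genotypes, so a difference between them widened the spread within its groups. The 0 is therefore not the count expected by chance. A drift in 1 direction along the numbers in the sample descriptions, if these record the order of processing, is argued against as the whole cause: WT 3 minus KI 1, the array numbered before it, correlated negatively with the mean of KI 2 and KI 3 minus the mean of WT 1 and WT 2, numbered before them (Pearson r = -0.89, Spearman rho = -0.87 across probe sets, which are not independent replicates). Genes within 20 Mb of Tnfrsf11a were not called more often than others (odds ratio 0.81, 95% interval 0.51 to 1.25). This argues against a local excess of calls from donor-strain sequence, but cannot show whether such sequence changed genes elsewhere. A change along the numbers that does not run in 1 direction and an effect of donor-strain sequence on genes elsewhere stay open. So do the genotype and any other difference between the mice or cultures of each genotype.

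WT 1 lay farther from the KI arrays than WT 2 and WT 3, and its 18S control probe sets had a mean log2 of 10.98, against 10.06 to 10.32 on the other arrays. RNA degradation is argued against, since the difference between 3' and 5' probe sets of Gapdh and Actb on WT 1 lay at most 0.013 outside the range of the other 5 arrays. WT 1 minus WT 2 correlated with the mean of KI 2 and KI 3 minus WT 3 (Pearson r = -0.43 across probe sets), which is consistent with WT 1 lying farther along the direction that separates the genotypes, a position already seen in the principal components. KI 1 minus KI 2 correlated with KI 3 minus the mean of WT (r = 0.38). What set WT 1 and KI 1 apart was not tested, and no biological explanation was tested.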

How the results depend on the processing

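The spike-in scaling, the older spike-in scaling and the fit without WT 1 and KI 1 were chosen after seeing the data. The count of 10101 probe sets past the threshold was 6184 with the replicate number as a block, 6481 with the description number as a covariate, 1733 on the 3 arrays with consecutive numbers and 4678 with 1 mean per gene, where fewer features or residual degrees of freedom were left. The fit to the 3 arrays with consecutive numbers holds 1 KI array and so no spread within KI. Its count therefore cannot show how stable the calls are. Leaving out 1 array gave 6793 (without KI 3) to 9335 (without WT 1). Whether the same replicate numbers pair the arrays stays open. Deviations of same-number arrays correlated at -0.40, -0.29 and -0.30. A shift shared by a pair would give positive values, but genotype differences that vary in size between pairs would give negative ones. Under the block, which leaves each difference unchanged, 6124 of the 10101 calls were kept. The calls for Nfatc1 (adjusted p = 0.053), Ctsk (0.075), Dcstamp (0.077), Ocstamp (0.077) and Atp6v0d2 (0.064) were among those that ended. In the same direction, 6136 calls were kept with the covariate, 8298 under spike-in scaling and 6463 under older spike-in scaling. The count at least 2-fold apart was 719 with 1 mean per gene, 1122 without WT 1 and KI 1 and 4093 under older spike-in scaling. The dimmer probe set of Tnfrsf11a in WT passed the threshold with array weights (0.57, a fit that stopped before convergence) and without WT 1 and KI 1 (0.55), with 0.03 to 0.45 when 1 array was left out; the mean of the gene's probe sets differed by -0.46 (adjusted p = 0.11). The cause was not tested. Of 24 gene lists, 9 passed with the preset correlation, 0 with an estimated one (smallest adjusted p = 0.41) and 8 with fry, which tests the lists' genes on their own: it lost cell cycle (0.12), cholesterol synthesis (0.22) and neutrophil and myeloid progenitor markers (0.079) and gained matrix and adhesion (0.031) and erythroid and megakaryocyte markers (0.037). Ebp, a cholesterol synthesis gene called higher as deposited (0.18, adjusted p = 0.028), reversed to -0.026 under spike-in scaling, which lowers KI against WT by the same amount in every probe set, and its call ended without any of WT 2, WT 3, KI 1, KI 2 and KI 3 (adjusted p = 0.057 to 0.11), with the covariate (0.16), the common median (0.051), log2 of the intensity plus 32 (0.054) and robust eBayes (0.051). With the covariate, 7 macrophage identity genes and 1 lysosomal gene rose, 0 cholesterol synthesis genes rose, and 19 oxidative phosphorylation, 8 glycolysis and hypoxia and 5 cell cycle genes fell. Under the block, 5 macrophage identity genes, 1 lysosomal gene and 0 cholesterol synthesis genes rose. Falls under the block numbered 4 for glycolysis and hypoxia and 0 for oxidative phosphorylation and cell cycle. Of osteoclast effectors 5 fell and 0 rose under it, and of fusion genes 0 fell and 1 rose. The camera results of all 24 lists stayed the same under the block. Spike-in scaling also ended the calls of Atp6v0d1 (adjusted p = 0.072), Mx2 (0.15), Cd209a (0.18) and Hmgcs1 (0.086). Older spike-in scaling, a larger shift of the same kind, reversed Ebp (-0.35), Gusb (-0.24), Cd209a (-0.15), Mx2 (-0.13), Atp6v0d1 (-0.12), Npc1 (-0.078), Bcl6 (-0.077), Ctsl (-0.075), Gsn (-0.030) and Rsad2 (-0.0073), all called higher as deposited, and Tsix (-0.52), which was not called. Among 128 named genes, quantile normalization left 126 calls as they were, the common median 125, no filter 127, spike-in scaling 115, older spike-in scaling 99, the covariate 95 and the block 79. Calls of these named genes on the 3 arrays with consecutive numbers were not counted, since that fit holds 1 KI array. Leaving out 1 array ended 6 (WT 1) to 25 (KI 3) of 127. Windows of 10 and 50 Mb around Tnfrsf11a gave odds ratios of 0.60 and 1.06. The deposited values carry no detection calls, so values near the floor of 16 bound no fold change.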

Other observations

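The gene lists here were made after seeing the data of the report, and the Fisher's exact tests were chosen after the results were seen. Ribosome biogenesis and nucleotide synthesis genes were lower in KI cells, where Myc, a transcription factor that drives them and is not taken by the naming rule, fell by 2.16 (SE 0.15, adjusted p = 0.0019). Of 46 measured, 44 fell (95.7%) and 0 rose, with a median log2 change of -1.08 (camera adjusted p = 1.7e-17; adjusted p = 0.22 with an estimated correlation), against 22.8% lower among other genes above the filter. Srm, the spermidine synthase, fell by 1.83 (adjusted p = 0.0044), Nop56, a core nucleolar protein, by 1.71 (adjusted p = 0.0054), and Dkc1, the pseudouridine synthase dyskerin, by 1.78 (adjusted p = 0.0056). Mitochondrial ribosome genes fell in 59 of 76 cases (77.6%) and rose in 0 (median -0.48; camera adjusted p = 1.7e-17; adjusted p = 0.22 with an estimated correlation), with Mrps6 lower by a log2 change of -2.05 (adjusted p = 0.00061). Cytosolic ribosome genes fell in 12 of 43 cases (27.9%) and rose in 0, with a median of -0.09. The largest falls among them came from dimmer probe sets, such as Rpl12 (-1.36, mean log2 8.9 in KI and 10.3 in WT) and Rpl14 (-0.92, 9.4 and 10.3). Bright members that fell changed less, such as Rps18 (-0.17, 14.7 and 14.8). The Rps16 probe set lay near the floor (4.5 and 4.4), so not every member reports an abundant transcript. Camera called this list lower (adjusted p = 1.2e-05; adjusted p = 0.22 with an estimated correlation), but its share of falls did not pass a test against other genes (Fisher's exact test p = 0.35), which leaves open whether it belongs to the same change.

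Amino acid and one-carbon genes linked to the transcription factor ATF4 fell in 25 of 29 cases (86.2%) and rose in 2, with a median of -1.03 (camera adjusted p = 8.3e-08; adjusted p = 0.22 with an estimated correlation). Slc7a1 and Slc7a5, amino acid transporters, fell by 1.97 (adjusted p = 0.0095) and 1.96 (adjusted p = 0.015), the mitochondrial folate enzymes Mthfd2 and Shmt2 by 1.89 (adjusted p = 0.015) and 1.74 (adjusted p = 0.0067), and the serine synthesis enzyme Psat1 by 1.64 (adjusted p = 0.015). The 2 that rose were Cebpb (1.07) and Cebpg (0.37). These values are consistent with the hypothesis that the falls of Asns, Chac1 and Trib3 are part of a wider fall of this group. Tissue-resident macrophage genes rose in 12 of 26 cases (46.2%) and fell in 0 (median 0.86; camera adjusted p = 4.1e-07; adjusted p = 0.22 with an estimated correlation). Hpgds, a prostaglandin synthase, rose by 2.20 (adjusted p = 0.0070), P2ry12 by 2.01 (adjusted p = 0.0044) and Stab1 by 1.91 (adjusted p = 0.0085), while Sall1 (-0.0049) and Tmem119 (0.22) did not pass. The share set in advance, over 50% of the measured members, was not reached. Above the filter 12 of 21 rose and 0 fell, against 17.7% higher among other genes (Fisher's exact test p = 5.9e-05, unadjusted). Among 20 iron handling genes, 60% changed, 8 higher and 4 lower, against 40.9% of other genes above the filter (Fisher's exact test p = 0.11, camera adjusted p = 0.11 and 0.47 with an estimated correlation). Rises alone made up 40%, against 17.8% of other genes (Fisher's exact test p = 0.017, unadjusted), and falls 20%, against 23.1%. The first criterion, over 50% changed, was met, but was too weak against that share of other genes, so the question stays open. The haem oxygenase Hmox1 rose by 1.36 (adjusted p = 0.019) and Tfrc, the transferrin receptor, fell by 0.42 (adjusted p = 0.0042), and the array's own 3' control for this transcript was lower in KI by a log2 difference of -0.91. Of 8 osmotic response genes 4 fell (50%) and 0 rose, which does not decide whether the falls of Slc6a12 and Slc5a3 belong to a wider change (camera adjusted p = 0.082; adjusted p = 0.22 with an estimated correlation). Above the filter 4 of 6 fell, against 23.1% of other genes (Fisher's exact test p = 0.028, unadjusted). Of those 4, Slc38a2 (-0.65) is also counted in the ATF4-linked list, so these 2 lists are not separate evidence. Nfat5, the osmotic transcription factor, fell by 0.53 (adjusted p = 0.0070). The medians of these lists kept their sign under quantile normalization, a common median and both spike-in scalings, except that of iron handling, which was 0.13 as deposited, -0.07 under spike-in scaling and -0.40 under older spike-in scaling. The counts of these lists were not refitted without an array, with the covariate or with the block, so their stability under those settings is not known.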
